A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

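The series profiled chromatin of budding yeast by ChIP-seq, the sequencing of DNA recovered with an immunoprecipitated (IP) protein. Sir2 and Hst1 are paralogous NAD+-dependent histone deacetylases. Per the labels' protocols, cells were grown at 30 °C in rich glucose medium to early log phase, and 50 OD of cells were crosslinked with 10 mM dimethyl adipimidate and then with 1% formaldehyde, for 1 hour each. Chromatin was sheared in 4 rounds of sonication of 10 seconds each and incubated with 5 µL of anti-HA antibody, and libraries were read in 50-cycle single-end runs. The 4 samples were an IP from a Sir2-HA strain, an IP from an Hst1-HA strain, a mock IP with the same antibody from the parental strain and a genomic input. The genomic input was not analysed here.

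Each of the 3 IPs had 1 peak list. Per the submitters' processing notes, the tools were BWA and MACS2 and the genome build was sacCer3; versions and cutoffs are not given in the sources used here. The series' design text names 2 technical replicates per IP. Whether these were pooled, and which library was the control of each call, is not given in the sources used here. Each peak had the authors' fold enrichment at its summit, a ratio of the pileup to the caller's local background. The authors' lists also gave −log10 p and −log10 q per peak, and the deposited score was 10 times the −log10 q cut to a whole number in all 159, 692 and 3 peaks. The fold per peak is the authors' caller's own value, and it was used to describe, rank, filter and compare peaks within a list, not between lists. The lists hold no read counts, so the sequencing depth is unknown. With 1 list per IP there was no replicate check, and every p describes these lists, not the conditions. Confidence intervals (95%, exact Clopper-Pearson) cover counting error only.

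Peak starts were converted to 1-based positions. Genes came from a RefSeq table of the R64 assembly, which is the assembly sacCer3 was made from, with 6002 protein-coding and 275 tRNA genes on the 16 nuclear chromosomes. The table gave no chromosome lengths, so the right end of a chromosome was taken as the last base of any gene or peak on it. A gene was called bound where a summit lay in the 500 bp upstream of its annotated start. Promoter peaks were those with a summit in such a stretch and outside all annotated genes, noncoding ones included. Telomere-proximal peaks had a summit within 10 kb of a chromosome end, and tRNA-proximal peaks had one within 500 bp of a tRNA gene. Peaks overlapped where they shared at least 1 bp.

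Shares of peaks were set against 10000 random placements of the peak summits on their own chromosomes (permutation, 2-sided, with a smallest possible p of 0.0002) and compared between the lists by 2-sided Fisher's exact test. The overlap of the lists was tested by 10000 random placements of whole Sir2 peaks, each keeping its length and chromosome. Differences in median fold were tested with 100000 permutations, 2-sided, with a smallest possible p of 1e-05. For each of 14 gene lists, the share of bound genes was set against all other protein-coding genes by 2-sided Fisher's exact test, adjusted by Benjamini-Hochberg over 28 tests. Genes of a list bound in only 1 of the IPs were compared by an exact McNemar test, adjusted over the 14 lists. The groups, tests, gene lists and the rule for named genes were fixed before the data were examined. That rule took the 10 peaks of highest fold in each list, up to 4 bound members of each gene list per IP, the silent mating loci, SIR2, HST1, SUM1, all mock IP peaks, and the 10 shared regions with the smallest sum of ranks. Genes named outside it were chosen after their values were seen. The symbols of 3 list members (QNQ1, MFALPHA1 and MFALPHA2) had no match in the gene table. The test of sequence motifs planned for the summits needed a genome sequence and was not run.

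Alternatives fixed in advance were a minimum −log10 q of 10, the strongest 50% of each list by fold, merging of peaks within 500 bp, removal of peaks overlapping a mock IP peak, other distances to ends, promoters and tRNA genes, other definitions of overlap, intergenic random positions, joint shifts of all summits, the omission of genes or peaks near chromosome ends, and lists cut to equal length. Added after the data were seen were summits inside genes, the Ty element genes, peaks in Ty genes left out, alone or with peaks near ends, left chromosome ends only, the PAU gene neighbourhoods, the overlap of interior Sir2 peaks, intergenic positions for tRNA genes, and the fold of peaks in list promoters. On simulated peaks of equal length at uniform random positions, 3 of 40 pairs of unrelated lists gave an overlap p under 0.05, and 5 of 5 lists with 60 planted overlaps did. The real lists have unequal lengths and cluster at ends and in promoters, so these runs do not show how the overlap test behaves on them. Random peak lists gave an adjusted call for a gene list in 0 of 40 runs over 6002 genes, and a list with 15 planted promoters was recovered in 10 of 10. The fold test called 2 of 40 unchanged sets and 40 of 40 shifted ones. The software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.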

Results

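Peak lists from HA-tag IPs of Sir2 and of Hst1, and from a mock IP of the untagged parental strain, were compared in early log phase yeast, with 1 list per IP. The question put to them was where each of these related deacetylases sits in the genome and how far their sites coincide. Sir2 is the catalytic subunit of the SIR complex, which silences the cryptic mating loci and subtelomeres, and it also acts at the ribosomal DNA (rDNA). Hst1 works with the DNA-binding protein Sum1 at genes of middle sporulation and NAD+ synthesis. The Sir2 list held 159 peaks over 254 kb, with a median length of 381 bp and a median fold of 2.48 (interquartile range 2.11 to 5.13). The Hst1 list held 692 peaks over 373 kb, with a median length of 400.5 bp and a median fold of 2.22 (interquartile range 1.88 to 3.15). The mock IP list held 3 peaks. All coordinates are sacCer3, and folds are the authors' deposited values.

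The mock IP peaks lay at TRP1, a tryptophan synthesis gene widely used as a marker, and at SIR3 and its neighbour ECM7. The TRP1 peak (IV, 461510 to 462651) had a fold of 5.32 and held the whole gene. The peak over most of SIR3, which encodes another SIR complex subunit, spanned XII, 1019503 to 1022059, with a fold of 2.48. The third peak (XII, 1022128 to 1023130) had its summit inside ECM7 and a fold of 2.34. Of the Sir2 peaks 0 of 159 and of the Hst1 peaks 0 of 692 overlapped a mock IP peak. Whether the mock IP was itself the control of the other calls is not given in the sources used here, and in that case shared background would already have been removed. The SIR2 and HST1 genes had no peak within 2 kb in any of the 3 lists.

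**Figure D1:**
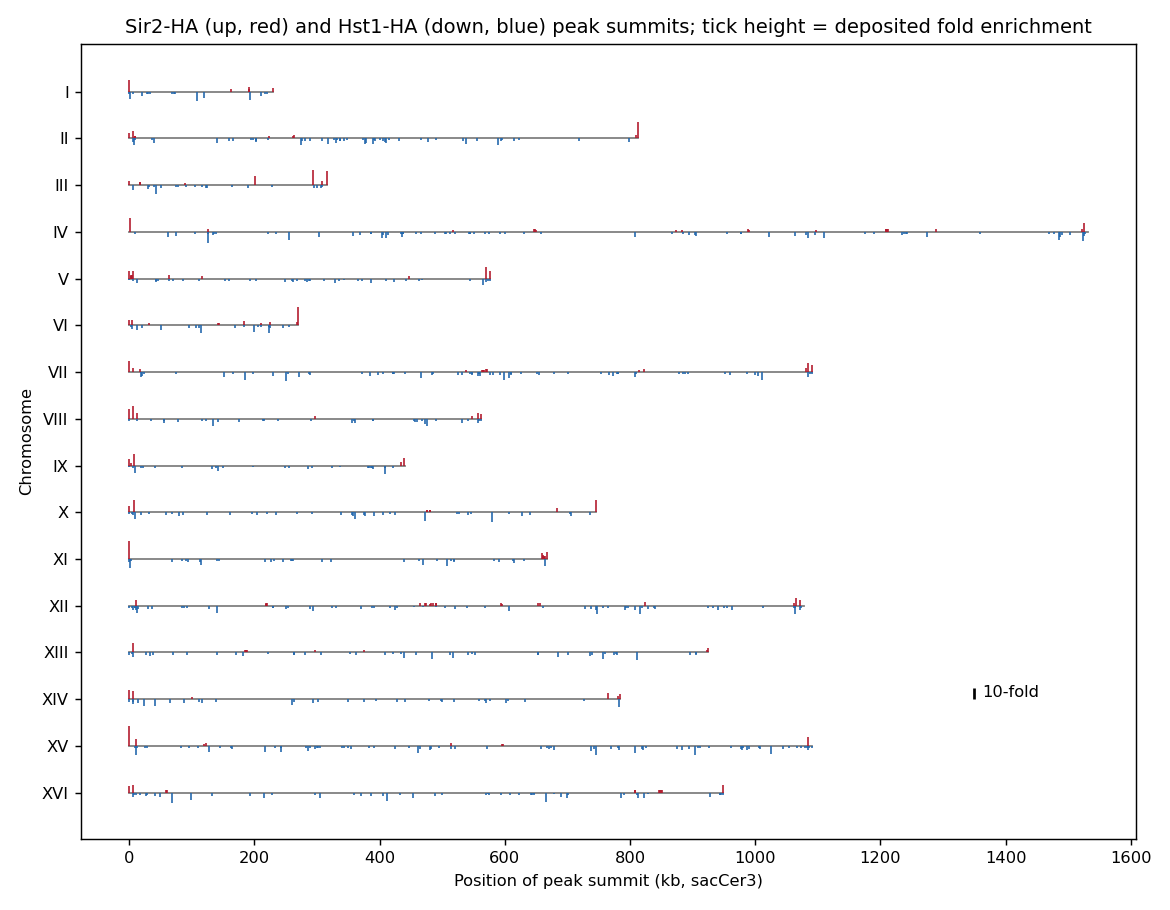
Summits of the 159 Sir2-HA peaks (red, upward) and 692 Hst1-HA peaks (blue, downward) along the 16 chromosomes (x axis, position in kb), with tick height proportional to the deposited fold (scale bar, 10-fold). Most tall Sir2 ticks stand at chromosome ends, where 63 Sir2 summits lie within 10 kb; those at HMR (fold 13.7) and MAT (fold 7.63) on III do not. Hst1 ticks run along the chromosome arms.

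Sir2 peaks clustered at chromosome ends. On the left arms, where the end is base 1 of the build, all 16 chromosomes had a Sir2 peak in the first kb, 15 had a peak from base 1 and 15 had a summit within 10 kb. On the right arms the last peak or gene set the end, a Sir2 peak on all 16, so contact with the end is not counted there. The 4 strongest Sir2 peaks were all at chromosome ends: next to YOL166W-A on XV (1 to 1936, fold 17.2), next to YFR057W on VI (269166 to 270161, fold 16.3), by PAU16 on XI (1 to 2906, fold 15.5) and by COS2 on II (811279 to 813184, fold 14.5). PAU genes encode seripauperin cell wall proteins and COS genes encode subtelomeric membrane proteins. Others among the 10 strongest lay by YCR108C on III (314822 to 316620, fold 12.5), COS7 on IV (1 to 1996, fold 12.3), COS5 on X (743825 to 745751, fold 11.1), YHL048C-A on VIII (2697 to 6466, fold 11.1) and PAU1 on X (2470 to 9933, fold 10.6).

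Telomere-proximal summits made up 63 of 159 Sir2 peaks (39.6%, CI 32.0 to 47.7), against 3.05% at random positions. The Hst1 list had 64 of 692 (9.25%, CI 7.20 to 11.7), against 2.73%. Both shares exceeded the random placements (permutation p = 0.0002 each, the smallest possible), and they differed by 30.4 percentage points (Fisher's exact p = 1.93e-18). The Sir2 share was 67.9% at a −log10 q of at least 10, 68.4% in the strongest 50% and 61.8% (63 of 102) with peaks in genes of Ty retrotransposons left out, a setting chosen after the data were seen. With left ends only, also chosen afterwards, 30 Sir2 and 37 Hst1 summits lay within 10 kb, a difference of 13.5 points (Fisher's exact p = 2.5e-07). The Sir2 peaks at ends were long, with a median of 1906 bp, and held 69.3% of all Sir2 peak sequence. Hst1 peaks at ends had a median length of 406.5 bp and a median fold of 2.06. On the left arms Hst1 had a summit within 10 kb on 15 of 16 chromosomes and a peak in the first kb on 9. Chromosome ends share near-identical sequence, so the placement of reads among them is uncertain.

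At the silent mating loci, which store unexpressed copies of the mating-type genes, Sir2 peaks covered all 4 genes completely. HMRA1 and HMRA2 lay in a 4466 bp peak (III, 291254 to 295719) with a fold of 13.7 and a −log10 q of 223, ranked 5 in the Sir2 list. HMLALPHA1 and HMLALPHA2 lay in a 16274 bp peak that ran from the left end of chromosome III to 16274, with a fold of 4.01 at a summit at position 289, close to the end and away from HML. A further Sir2 peak covered the expressed locus MAT (III, 198588 to 201207) with a fold of 7.63. Hst1 had no peak within 2 kb of the HML genes or at MAT, and next to HMR it had 1 of 644 bp (III, 295360 to 296003, fold 2.75) that covered neither HMRA gene. That Hst1 summit lay inside the noncoding gene YNCC0014W, so it does not show Hst1 at the silenced genes. The mock IP had no peak within 2 kb of these loci. HML, MAT and HMR share sequence, so reads from 1 of them may be placed at another.

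**Figure D2:**
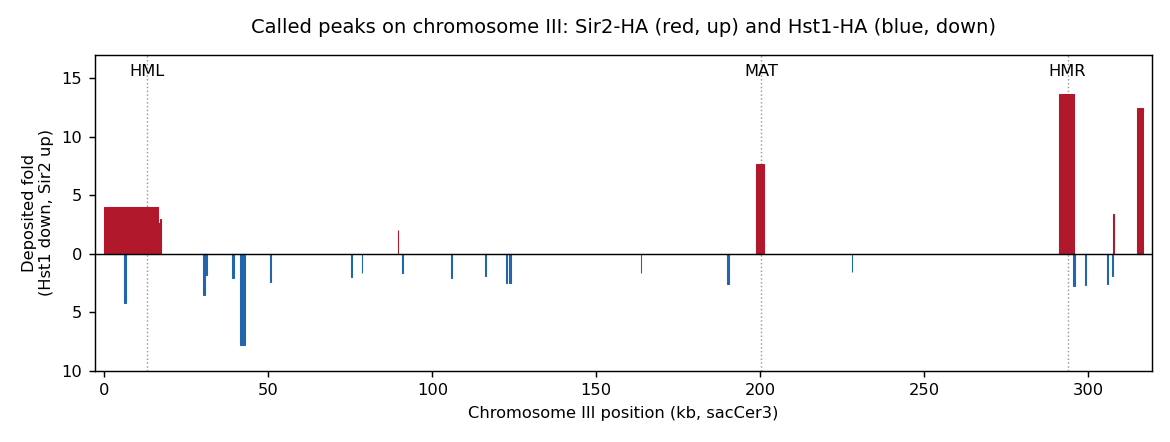
Called peaks on chromosome III (x axis, position in kb) for the Sir2-HA IP (red, upward) and Hst1-HA IP (blue, downward), each drawn at its called width with its deposited fold as height. Sir2 blocks cover HML (within the peak from 1 to 16274), MAT (fold 7.63) and HMR (fold 13.7). Hst1 has a peak beside HMR (fold 2.75), with its summit inside the noncoding gene YNCC0014W.

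In the region of the rDNA and its 5S genes on XII, Sir2 had 7 peaks and Hst1 had 3. Of the Sir2 peaks, 1 (473878 to 474107, fold 1.96) had its summit inside ASP3-2, an asparaginase gene between the 5S genes. A Sir2 peak from 451373 to 468982 with a fold of 2.54 spanned the annotated repeats, and the Hst1 peak there (451439 to 468541) had a fold of 1.35. Both lists also had a peak at RRT15, a gene beyond the spanned repeats (Sir2 peak 489797 to 490519), with a fold of 2.61 for Sir2 and 1.38 for Hst1. The rDNA is a long tandem array of which the build shows few copies, so the values of the peaks spanning the repeats average over copies.

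Promoters held Hst1 peaks more often than random positions did. Of 692 Hst1 peaks, 345 (49.9%, CI 46.1 to 53.6) were promoter peaks, against 15.8% at random positions (permutation p = 0.0002, the smallest possible). Of 159 Sir2 peaks, 18 were (11.3%, CI 6.85 to 17.3), against 15.7% (permutation p = 0.145). The difference was -38.5 percentage points (Sir2 minus Hst1, Fisher's exact p = 6.31e-21). Summits inside annotated genes made up 54.1% of Sir2 peaks and 24.3% of Hst1 peaks, both under the random 73.0% and 73.3% (permutation p = 0.0002 each, the smallest possible). They differed by 29.8 points (Fisher's exact p = 1.32e-12), but among peaks with a −log10 q of at least 10 by 8.57 points (Fisher's exact p = 0.0887) while in the strongest 50% the shares were 27.8% and 15.9% (Fisher's exact p = 0.0223). Of the 86 Sir2 summits inside genes, 57 lay in Ty genes. With those peaks left out, a setting chosen after the data were seen, the shares were 28.4% (29 of 102) and 24.1%, 4.37 points apart (Fisher's exact p = 0.328).

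The strongest Hst1 peak lay between PPH22, which encodes a protein phosphatase 2A catalytic subunit, and YDL186W (IV, 124946 to 126018, fold 9.46). Next came peaks with summits upstream of BBP1, a spindle pole body gene (XVI, 66777 to 68017, fold 8.75), and of SMK1, a spore wall MAP kinase gene, and NHP6A (XVI, 665571 to 666963, fold 8.57, summit inside YPR053C). Summits upstream of SAS5 (XV, 745165 to 746847, fold 8.24), which encodes a subunit of a histone acetyltransferase, of BNA2 (X, 577986 to 579565, fold 8.23) and BNA1 (X, 470876 to 472517, fold 7.92), which encode enzymes of NAD+ synthesis, and of the mannosyltransferase gene PMT2 (I, 108477 to 109400, fold 7.90, summit inside FUN26) followed. A peak between YGL138C and the coatomer gene SEC27 (VII, 248945 to 249948) had a fold of 7.87. The remaining peaks of the top 10 lay by PAU20 (XV, 10794 to 11846, fold 8.29) and PAU16 (XI, 603 to 2280, fold 8.09).

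**Figure D3:**
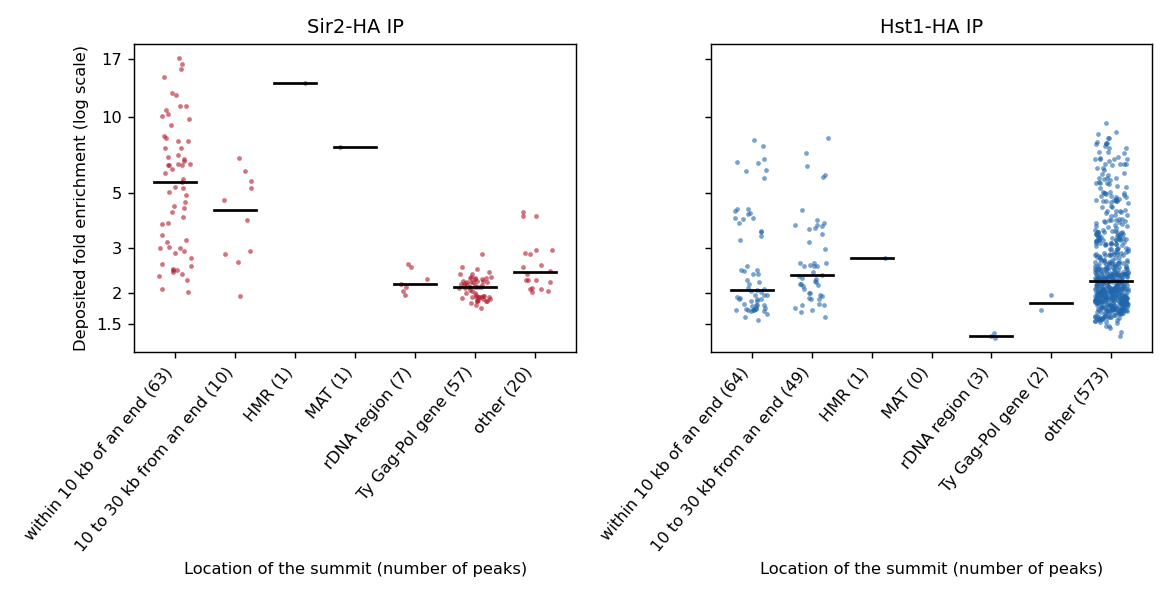
Deposited fold of each peak (y axis, log scale) by the location of its summit for the Sir2-HA IP (left, red) and the Hst1-HA IP (right, blue). Points are peaks, black lines are medians and numbers in brackets are peaks per class. Sir2 peaks within 10 kb of an end have a median fold of 5.53 and those in Ty genes 2.11, and 573 of the Hst1 peaks lie in none of the named classes.

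Promoters of middle sporulation genes, a list of spore formation genes that also held cell cycle and spindle pole body genes, were bound by Hst1 more often than those of other genes. Hst1 summits lay upstream of 27 of 55 such genes (49.1%, CI 35.4 to 62.9), against 8.04% of the other genes, an odds ratio of 11.0 (Fisher's exact adjusted p = 5.57e-14). The strongest were BBP1 (fold 8.75), SMK1 (8.57), the spore wall gene SPS22 (III, 41227 to 42736, fold 7.81) and SPS4 (XV, 901333 to 904517, fold 7.70). The promoter of NDT80, the transcriptional activator of middle sporulation, had a fold of 3.91. Sir2, with 28 bound genes in all, had 0 of 55, and the difference of 27 genes was past the threshold (exact McNemar adjusted p = 2.09e-07). Of 30 early meiosis genes, a comparator list, Hst1 bound 1, MAM1, a monopolin subunit gene (fold 2.41, Fisher's exact adjusted p = 1).

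Genes of NAD+ metabolism had Hst1 summits at 6 of 22 promoters (27.3%, CI 10.7 to 50.2, Fisher's exact adjusted p = 0.0448). These were BNA2 (fold 8.23), BNA1 (7.92), BNA5 (4.87) and BNA4 (3.67) of the kynurenine pathway, BNA6 (2.20), and NPT1 of the salvage pathway (4.24). Of 27 glycolysis and fermentation genes, 7 were bound (25.9%, CI 11.1 to 46.3, Fisher's exact adjusted p = 0.0402), with the strongest at PYK2, a second pyruvate kinase gene (3.42), the glucokinase gene GLK1 (2.39), TDH1 (2.33) and ADH5 (2.24). Sir2 bound 0 of 22 and 0 of 27, and with 6 and 7 genes apart neither difference passed (exact McNemar adjusted p = 0.109 and 0.0729). With genes within 10 kb of ends left out, which removed 0 members of these lists, the shares stayed the same and the odds ratios went from 4.12 to 4.11 and from 3.85 to 3.84. The adjusted p of both became 0.0526 (Fisher's exact) through the adjustment over all lists. The glycolysis share fell to 14.8% both at a −log10 q of at least 10 (Fisher's exact adjusted p = 0.219) and in the strongest 50% (Fisher's exact adjusted p = 0.133). With any part of a peak counted, Hst1 had 9 of 22 NAD+ and 11 of 27 glycolysis genes (Fisher's exact adjusted p = 0.00238 and 0.000832), and Sir2 had 0 of both.

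Other Hst1 lists did not pass the test against the remaining genes. Thiamine genes had 5 of 25 bound (Fisher's exact adjusted p = 0.188), with the pyrimidine synthesis genes THI5 (fold 3.80) and THI12 (3.71), near-identical copies, ahead of SNO1 and SNZ1, which share a peak (2.28). Among silencing factors 3 of 20 were bound (Fisher's exact adjusted p = 0.728): ORC3 (6.49, a peak shared with the sporulation gene SPO75), SUM1 itself (IV, 1084461 to 1085170, fold 5.73) and ABF1 (2.99). Mating type-specific genes had 2 of 24, the a-factor receptor gene STE3 (5.05) and PRM1 (2.07). Hexose and maltose uptake genes had 3 of 27, HXT14 (6.14), HXT9 (2.28) and HXT11 (2.07), and translation and chaperone genes 2 of 25, TEF2 (2.84) and TEF1 (2.24). These last 3 lists had Fisher's exact adjusted p = 1.

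Ribosomal protein genes had 14 of 137 bound by Hst1 (10.2%, CI 5.70 to 16.6), close to the 8.37% of other genes (Fisher's exact adjusted p = 1), and 0 by Sir2. RPS30B (fold 3.25), RPS9A (2.52), RPS18A (2.30) and RPL41B (2.21) were the strongest. Their difference between the IPs was past the threshold (14 genes, exact McNemar adjusted p = 0.000854), but with the Hst1 list cut to the Sir2 length it was 0 genes.

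**Figure D4:**
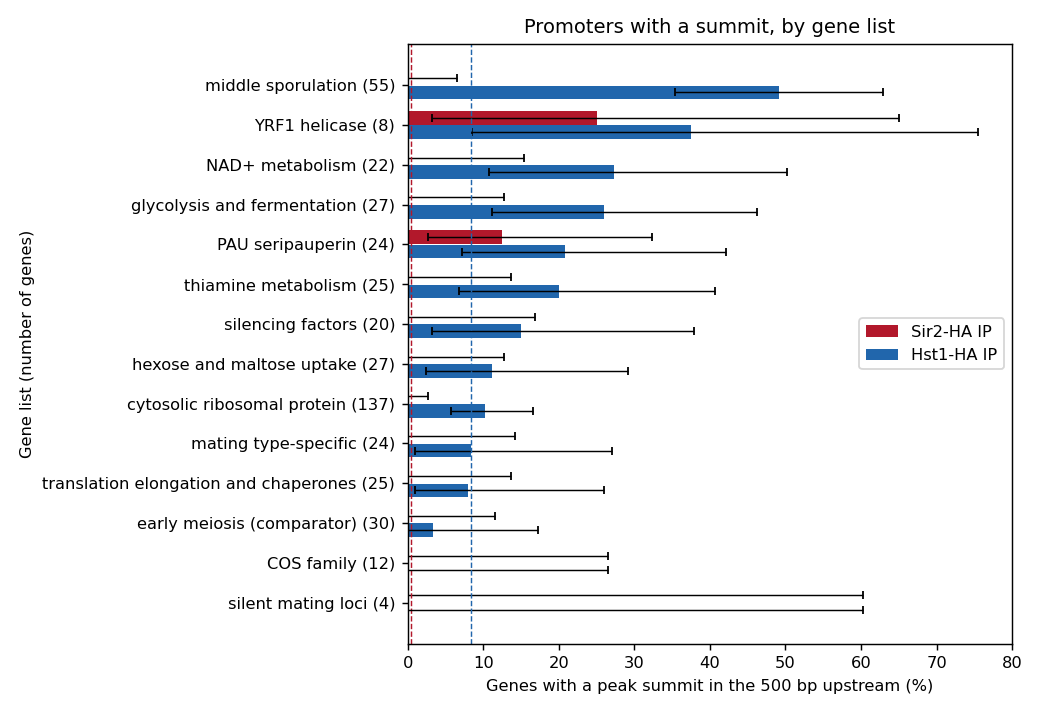
Share of each gene list (y axis, with the number of genes) that has a summit in the 500 bp upstream of its start (x axis, %), for the Sir2-HA IP (red) and the Hst1-HA IP (blue). Error bars are 95% exact Clopper-Pearson intervals and dashed lines are the shares over all 6002 genes. Middle sporulation genes reach 49.1% for Hst1, and Sir2 has bound genes in the PAU and YRF1 lists.

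Sir2 summits lay upstream of 28 genes, against 505 for Hst1. Of the fixed lists, PAU genes had 3 of 24 bound by Sir2 (Fisher's exact adjusted p = 0.00241), PAU3 (fold 3.38), PAU6 (2.47) and PAU15, with a fold between these. YRF1 genes, which encode subtelomeric helicases, had 2 of 8 (Fisher's exact adjusted p = 0.00539), YRF1-3 (7.50) and YRF1-7 (6.67). The other 12 lists had 0 bound genes for Sir2. Of these genes, 14 of 24 PAU and 8 of 8 YRF1 genes lay within 10 kb of ends, and with such genes left out Sir2 bound 0 of 10 PAU genes and 0 lists passed. Because Sir2 peaks at ends are long, a summit reaches few promoters: with any part of a peak counted, PAU genes had 17 of 24, COS genes 8 of 12, YRF1 genes 8 of 8 and the silent mating loci 4 of 4. For Hst1, PAU genes had 5 of 24 by summit (PAU18 2.55, PAU2 2.39, PAU20 2.13 and PAU3 1.93 the strongest, Fisher's exact adjusted p = 0.184). YRF1 genes had 3 of 8 (YRF1-6 4.31, YRF1-3 4.14 and YRF1-7 4.10, Fisher's exact adjusted p = 0.112), COS genes 0 of 12 and the silent mating loci 0 of 4. With any part of a peak counted, Hst1 had 10 of 24 PAU genes and 6 of 8 YRF1 genes, both past the threshold (Fisher's exact adjusted p = 0.00114 and 0.000387). The YRF1 list also passed for Hst1 with the same 37.5% at a −log10 q of at least 10 and in the strongest 50% (Fisher's exact adjusted p = 0.0399 and 0.0254) and with 87.5% for 1000 bp promoters (Fisher's exact adjusted p = 3.84e-05). With summits inside genes, chosen after the data were seen, it passed with 75% (Fisher's exact adjusted p = 3.48e-08). In these settings the PAU list did not pass for Hst1. Members of these families are near-identical, and reads may be placed at the wrong copy.

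Regions bound in both IPs lay mostly near chromosome ends. Of Sir2 peaks, 46 of 159 (28.9%) overlapped an Hst1 peak, where random placement gave 16.5 peaks, or 10.4% (95% range 10 to 24 peaks, permutation p = 0.0002, the smallest possible). They met 79 of 692 Hst1 peaks (11.4%), and 30 of the 46 lay within 10 kb of an end. Intergenic random positions gave 18.0% in place of 10.4% (permutation p = 0.0012), and with peaks in Ty genes left out, a setting chosen after the data were seen, the overlap was 45.1%. The shared regions of best joint rank, named by the gene at the Hst1 summit, were by PAU16 (XI, Sir2 fold 15.5 and Hst1 fold 8.09), PAU10 on IV (8.05 and 7.70), PAU20 (6.08 and 8.29), PAU8 on I (10.1 and 6.63), PAU14 on IX (10.3 and 6.56), PAU4 on XII (6.89 and 7.17), PAU1 (10.6 and 5.75) and PAU9 on II (6.51 and 6.15), then SWH1 on I (4.05 and 7.24) and PAU6 on XIV (4.20 and 6.83). Each Sir2 fold belongs to the summit of the Sir2 peak, which lay 8 bp from the Hst1 summit at PAU20 and 868 to 1716 bp from it in the others. Other genes were nearest to it at PAU10 (YRF1-1), PAU4 (YLR462W), PAU9 (YBL111C), SWH1 (YAT1) and PAU6 (YNR077C). YAT1 encodes a carnitine acetyltransferase and SWH1 an oxysterol-binding protein homologue. With peaks within 10 kb of ends left out, 16 of 96 Sir2 peaks (16.7%) still overlapped, against 6.54% at random (permutation p = 0.001). With Ty peaks left out as well, these were 16 of 39, against 9.66% (permutation p = 0.0002, the smallest possible). Of the 16, however, 6 had a summit 10 to 30 kb from an end, 1 lay at HMR, 2 lay in the rDNA region and 7 lay elsewhere.

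Sir2 peaks that overlapped an Hst1 peak had a higher fold, with a median of 5.47 in 46 peaks against 2.25 in 113 others, a difference of 3.22 (permutation p = 1e-05, the smallest possible). With peaks within 10 kb of ends left out, the difference was 0.752 (permutation p = 5e-05), but 57 of the 96 peaks left lay in Ty genes, and 0 of these overlapped. In settings chosen after the data were seen, it was 2.56 without Ty peaks (permutation p = 0.00227) and 0.632 without Ty peaks and peaks at ends (16 peaks against 23, permutation p = 0.0427). The 79 shared Hst1 peaks had a median fold of 2.10 against 2.23 in 613 others (permutation p = 0.239). That difference turned to 0.762 in favour of shared peaks at a −log10 q of at least 10 (permutation p = 0.00573). In all of these settings fold was compared without regard to peak length, and a longer peak meets another list more readily. Sir2 peaks within 10 kb of ends had a median length of 1906 bp and a median fold of 5.53, against 293 bp and 2.11 in Ty genes. Length may therefore account for some or all of the Sir2 difference, which was not tested.

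Genes for tRNAs had Hst1 summits nearby more often than random positions did. Of 692 Hst1 peaks, 89 (12.9%, CI 10.5 to 15.6) lay within 500 bp of a tRNA gene, against 2.43% (permutation p = 0.0002, the smallest possible). Of 159 Sir2 peaks 2 did (1.26%, CI 0.153 to 4.47), against 2.55% (permutation p = 0.446). The lists differed by -11.6 percentage points (Sir2 minus Hst1, Fisher's exact p = 1.22e-06). This share was planned because highly transcribed loci can give unspecific ChIP signal in yeast. Such signal cannot be told apart from Hst1 binding with these lists, here or at ribosomal protein, glycolysis and translation genes. Against intergenic positions, chosen after the data were seen, the expected shares were 6.52% for Hst1, still exceeded (permutation p = 0.0002, the smallest possible), and 6.77% for Sir2, which lay below it (permutation p = 0.002). Of the 159 Sir2 summits, 86 lay inside genes, so intergenic placement does not match that list. The Sir2 shortfall is therefore no evidence that Sir2 avoids tRNA genes.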

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

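The tests of Ty elements, of the mock IP peaks and of the MAT peak were chosen only after the results were seen, and the differences between the IPs were planned. Between the IPs, tests of the difference itself set apart the middle sporulation genes (27 more bound by Hst1 than by Sir2), the ribosomal protein genes (14 more), the telomere-proximal share of peaks (30.4 percentage points, Sir2 minus Hst1), the promoter share (-38.5 points), the share inside genes (29.8 points, but 4.37 with peaks in Ty genes left out) and the tRNA-proximal share (-11.6 points). The Sir2 list is shorter, so counts of bound genes differ partly through list length: with equal lengths, the ribosomal protein difference was 0, and the middle sporulation difference was 23 genes (exact McNemar adjusted p = 3.34e-06).

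Sir2 summits also lay in 57 places inside Gag-Pol genes of Ty retrotransposons, which no planned comparison covered and where the mock IP had 0 peaks. They made up 35.8% of Sir2 peaks against 1.94% at random positions (permutation p = 0.0002, the smallest possible) and fell in 27 of 31 Ty1, 5 of 10 Ty2, 0 of 2 Ty3 and 0 of 3 Ty4 genes. Their folds were low, with a median of 2.11 (1.74 to 2.84). Hst1 had summits in 2 Ty genes, with folds of 1.70 and 1.95.

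If both calls used the same kind of control, counts argue against background common to both anti-HA IPs as the cause of the Ty peaks. There were 31 Ty genes with a Sir2 summit only and 1 with an Hst1 summit only (exact McNemar p = 1.54e-08). The test takes each Ty gene as independent, but near-identical copies can rise or fall together, so this p overstates the evidence. Reads spread over near-identical copies may contribute: 69.6% of the 46 genes had a summit and fold varied little (interquartile range 0.296). Other Sir2 peaks of no higher fold had 0.459, and the spreads did not differ past the threshold (permutation p = 0.0882). That comparison set, however, included peaks less than 30 kb from ends. It also held peaks whose nearest gene was a Ty gene, such as that 1001 bp from YLR035C-A on XII. Such peaks may share the Ty signal, so the test cannot decide this explanation. More Ty copies in the Sir2-HA strain than in the control also stay open, since peaks covered 8.05% of a Ty gene on average and a weak gain over whole elements could fall under the caller's threshold. Sir2 residing at Ty1 elements is an untested biological alternative.

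The mock IP peaks at TRP1, SIR3 and ECM7 were weighed next. Recovery by the antibody alone cannot be told apart from the rest, because the tagged IPs had 0 peaks within 2 kb of the 3 genes, which a mock IP used as their control would also give. The TRP1 peak held the gene with margins of 332 and 135 bp, and the pair of peaks over SIR3 and ECM7 lay 68 bp apart. Extra DNA copies of these genes in that library were not tested, since the lists hold no copy numbers, and no biological explanation was tested.

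At MAT, the Sir2 peak covered both alpha genes and reached 958 and 238 bp beyond them. The alpha genes span 1424 bp at MAT and at HML, a difference of 0 bp that copies of the same genes would give in any case. How far the shared sequence runs past the genes was not examined, since no genome sequence was at hand. Reads shared with the silent mating loci may add to this peak. The lists hold no reads, and binding at MAT itself cannot be told apart from such reads.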

How the results depend on the processing

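Summits inside genes, Ty peaks left out, left chromosome ends only, intergenic positions for tRNA genes and most settings of the comparison of bound genes between IPs were chosen after the data were seen. Of 154 values that answer a comparison, 126 kept direction and call or stayed within 1.5 times; of 348 values for single gene lists, 320 kept theirs, 13 gained and 9 lost the call and 6 reversed. Removing peaks that overlap a mock IP peak removed none. All values of that setting, 42 of the 320 among them, were therefore kept by construction, as were the counts of bound genes under joint shifts. At a −log10 q of at least 10, 78 Sir2 and 414 Hst1 peaks were left, Hst1 bound 324 genes, 1 list differed between IPs, shares inside genes differed by 8.57 points and shared Hst1 peaks had a fold 0.762 higher. In the strongest 50%, these were 79 and 346 peaks, 276 genes, 1 list, shares of 27.8% and 15.9% and a difference of 1.02; glycolysis lost its call in both. With 1000 bp promoters, Sir2 bound 55 and Hst1 774 genes. With any part of a peak counted, Sir2 bound 115 genes, 4 Sir2 and 5 Hst1 lists passed, 5 differed between IPs, and the Sir2 share reversed to 100% of the silent mating loci and 66.7% of COS genes, by construction of longer peaks. Under joint shifts of all summits, 7 Hst1 lists passed; shifts also move summits out of promoters, so the general preference of Hst1 for promoters adds to these calls. With genes within 10 kb of ends left out, Sir2 bound 18 genes and 0 Sir2 lists and 1 Hst1 list passed, with 0% of PAU genes bound by Sir2; the NAD+ and glycolysis lists, with 0 members there, kept their shares and lost the call through the adjustment only. With summits inside genes counted instead, Sir2 hit 59 and Hst1 116 genes, 1 Sir2 list passed, 0 lists differed between IPs, and the share was 0% for YRF1 genes under Sir2 and for NAD+ and glycolysis genes under Hst1. At equal list lengths 1 list differed. With Ty peaks left out, shares inside genes differed by 4.37 points. Against intergenic positions, the Sir2 tRNA share of 1.26% fell under the expected 6.77% (permutation p = 0.002), but 86 of the 159 Sir2 summits lay inside genes, which such placement does not match. Where not stated, the cause was not tested. Motif alternatives were not run. Depth is unknown, so weak sites missing from a list are not shown to be unbound. No paired analysis was possible because each IP had 1 list.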

Other observations

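The counts and tests in this part, on PAU genes, tRNA genes, interior Sir2 peaks and the fold of list promoters, were all chosen only after the peaks were seen. Several of the strongest Hst1 sites at chromosome ends lay just downstream of PAU genes. Summits stood 283 to 390 bp past the end of 10 of them, PAU1, PAU4, PAU6, PAU8, PAU9, PAU10, PAU14, PAU16, PAU18 and PAU20, with a median fold of 6.73 (5.75 to 8.29). Summits upstream of PAU18 (2.55), PAU2 (2.39), PAU20 (2.13), PAU3 (1.93) and PAU4 (1.71), and those inside PAU13 (1.96), PAU22 (1.81) and PAU21 (1.65), had lower folds. Within 30 kb of an end, 14 of 19 PAU genes (73.7%) and 67 of 370 other genes (18.1%) had an Hst1 summit within 500 bp. For Sir2 these were 9 of 19 (47.4%) and 33 of 370 (8.92%). PAU neighbourhoods are near-identical, so these genes are not independent sites.

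Of 20 Sir2 peaks more than 30 kb from ends and outside Ty genes, rDNA, MAT and HMR, 7 overlapped an Hst1 peak, where random placement gave 1.25 (permutation p = 0.0008). The 7 met 6 Hst1 peaks, since 2 adjacent Sir2 peaks at YAT1 overlapped the same one. With these merged, 6 of 19 overlapped against 1.20 at random (permutation p = 0.0014). Both placements were anywhere on the chromosome, whereas Hst1 peaks favoured promoters, and intergenic placement was not run for these peaks. At PPH22 and YDL186W, the strongest Hst1 site, the Sir2 peak (IV, 125332 to 125569) had a fold of 2.58 and its summit was 8 bp from that of Hst1. The others lay at YAT1 (2 peaks, Sir2 fold 4.05 and 2.09), YFR018C on VI (4.17), CDC14 (2.26), QCR6 and PHO4 (2.84) and CRC1 (2.95). Their Hst1 partners had folds of 7.24 at YAT1, 1.83 at YFR018C, 1.89 at CDC14, 2.10 at QCR6 and 2.38 at CRC1. Background common to both anti-HA IPs was not tested at these sites. Interior Sir2 peaks without an Hst1 peak included URA3, a uracil synthesis gene (V, 116115 to 116667, fold 2.21), and a site by the sulfite reductase gene MET5 (X, 683569 to 684366, fold 4.02). The URA3 peak covered 62.3% of the gene itself. Extra DNA copies of URA3 in that library were not tested, since the lists hold no copy numbers.

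For the fold of list promoters, all 412 Hst1 peaks with a summit in the 500 bp upstream of a gene were used, inside another annotated gene or not. Those of middle sporulation genes were stronger than the rest, with a median fold of 5.22 in 27 peaks against 2.27 in 385 (permutation adjusted p = 5e-05), as were those of NAD+ genes (4.55 in 6 peaks against 2.30, permutation adjusted p = 0.0258). Peaks in ribosomal protein promoters had a median of 2.00 against 2.33 (permutation adjusted p = 0.338), in glycolysis promoters 2.24 against 2.33 and in PAU promoters 2.13 against 2.33 (permutation adjusted p = 0.794 for both). Hst1 summits lay within 500 bp of 94 of 275 tRNA genes (34.2%), and the 89 peaks there had a median fold of 2.00 against 2.27 in the other 603 (permutation p = 0.00664).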
